A study of Mus musculus with 4 samples.

How the data were processed

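RNA was measured by sequencing of poly(A)-selected libraries (Illumina TruSeq RNA kit v2, per the labels' protocols) from RN2 cells, a mouse acute myeloid leukaemia line driven by the MLL-AF9 fusion and mutant Nras. The cells carried a hairpin RNA switched on by doxycycline and were harvested after 48 h of doxycycline, per the labels' protocols. The series holds 4 samples in 2 groups of 2: a control group with a hairpin against Renilla luciferase, which mouse cells lack, and a knockdown group with 2 different hairpins against Med8, named shMed8.933 and shMed8.934. Each Med8 hairpin has 1 library, and the 2 hairpins were taken as the replicates of the knockdown group. Nothing in the labels says whether the control libraries came from separate cultures. The spread behind the p-values is only that between the 2 Med8 hairpin libraries, because the control enters as 1 value, as described below. That spread mixes any difference between the hairpins with technical spread.

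The submitters' processing notes name TopHat, Cufflinks, Cuffdiff and the mm9 build, with neither versions nor settings. The authors deposited 1 table with a block for each Med8 hairpin, and per the file headers each block gives a gene, its locus, its FPKM (fragments mapped to a transcript, scaled to its length and to the library size) and a log2 fold change against the Renilla control. After this scaling the reads behind a value are unknown, and no counting interval or detection floor is given. The control libraries had no columns of their own. A control FPKM was recovered for each gene as the deposited FPKM divided by the deposited fold, and the values from the 2 blocks were equal within 0.0014% for all 8057 analysed genes. Whether this value pools both control libraries is not given in the sources used here. It carries no measured spread. The lowest control FPKM was 5.0025, so genes low in control cells are not in the list, and a gene switched on from a low level would not be seen.

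Of 8281 listed genes, 224 were left out because their deposited fold was a stand-in in at least 1 block, either for an FPKM of 0 or as an exact 0. Among them, 143 of 154 genes with an exact 0 fold in both blocks and an FPKM above 0 in both had FPKM values that differed between the blocks by over 1%. They included 63 microRNA genes. A spreadsheet had turned 15 symbols into dates, and these genes were joined by locus and left unnamed. The analysed genes included 79 small RNA genes, and 862 analysed genes had a locus identical to that of another analysed gene. The 862 include Atf5, Gnl3, Bcl2, H2-D1 and H2-L, named below, whose values may hold reads of another gene. Loci are given as deposited, on mm9, with 1 added to the start, because end minus start equalled the RefSeq gene length for 2150 genes and end minus start plus 1 for 193.

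The test fixed before the data were examined was limma with an intensity trend on log2(FPKM + 1), in genes with a mean FPKM of at least 1, over 4 libraries. Because the control came as 1 value, it was fitted to 3 columns, 1 control and 2 knockdown. That leaves 1 residual degree of freedom per gene beside a prior of 4.97, and assumes that the control value varies like a hairpin library. Fold changes are on the log2(FPKM + 1) scale, which understates changes of low genes. All tests were two-sided, with Benjamini-Hochberg adjustment and a threshold of 0.05. The 31 gene lists fixed in advance were tested with camera at a preset inter-gene correlation of 0.01, where at least 5 members were measured, which held for 26 lists. Camera with an estimated correlation and fry were run beside it. Analyses used R 4.3.3, limma 3.58.1, Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9.

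The procedure was tested on simulated data for this comparison, with 8057 genes in each of 20 runs. Noise was resampled from the differences between the hairpins among genes of like level, after the median difference at each level was taken out. Of 200 changed genes per run, 20.3% of those changed 1.5-fold, 89.0% of those changed 2-fold and 99.5% of those changed 4-fold were found, with 30.0 false calls per run on average. With no change at all, limma called 14.2 genes per run on average and up to 28, and 17 of the 20 runs called at least as many genes as the real data. With normal noise of the same size it called 0.1 per run. The excess comes with heavy tails of the noise, since the hairpin differences had a kurtosis of 42.4 across genes. Camera called 0 lists with no change and 100% of 3 lists with a planted change of 0.3 on the log2 scale, in simulated noise that was independent between genes. The same planted lists were found in 0% with an estimated correlation and in 3.33% with fry, so a miss by either says little in this design.

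Agreement between the hairpins was measured across genes, which are not independent replicates, beside 100 simulations of unchanged libraries sharing 1 control. Those simulations draw their noise from the hairpin differences, which include any true difference between the hairpins. Transcript length and GC content, from GENCODE vM21 transcripts, were matched for 7995 genes (99.2%), 344 of them through a synonym. Each value was the median over a gene's protein-coding transcripts, or over all its transcripts where it had none. It can differ from that of the transcript expressed in these cells. Alternatives fixed in advance were pseudocounts of 0.1 and 5, no filter and a mean FPKM of at least 5, quantile normalization, median-of-ratios rescaling over genes with an FPKM of at least 5 in every column, limma without the trend or with a robust prior, a size threshold, and leaving out each library. Alternatives added after the data were seen left out small RNA genes, took out a trend on transcript length, or varied the settings of the counts of genes at least doubled or halved. Named genes were Med8, the 12 largest rises and falls past the test with a mean FPKM of at least 5 in the higher group and both hairpins on the same side (all, if fewer passed), up to 4 members with the smallest p of each list described, and a set fixed in advance (Myc, Bcl2, Cdk6, Myb, Kit, Hoxa9, Meis1, Itgam, Csf1r, Cd14, Mpo, Brd4, Med12, Med13, Med23, Med24, Actb, Gapdh). Predicted, unnamed and small RNA genes were skipped.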

Results

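The series measured messenger RNA in RN2 leukaemia cells 48 h after induction of a hairpin, to ask which genes depend on Med8, a subunit of the head module of the Mediator complex that links transcription factors to RNA polymerase II. The control group had 2 libraries with a Renilla hairpin, represented in the table by 1 control value per gene, and the knockdown group had 2 libraries, 1 for each Med8 hairpin. FPKM values were compared for 8057 genes, and the depth of each library is unknown. Values of single libraries and of the control have no replicate error of their own, and standard errors are limma's.

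Med8 (chromosome 4, 118081942 to 118088387, mm9) was lower in both hairpin libraries than in the control. Its FPKM was 35.7 in the control, 9.06 with hairpin shMed8.933 and 10.6 with hairpin shMed8.934. The log2 change was -1.77 ± 0.13 (SE, 2 hairpins against 1 control value), and the limma adjusted p was 0.0413. The labels and the level of the targeted gene go the same way.

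Besides Med8, 4 genes passed limma's test over all 8057 genes, and all 4 rose. Xdh, the purine-degrading enzyme xanthine dehydrogenase (chromosome 17, 74233235 to 74299536), went from an FPKM of 7.66 to 21.7 and 20.03 with hairpins shMed8.933 and shMed8.934. Ifitm3, an interferon-induced antiviral membrane protein (chromosome 7, 148195489 to 148196643), went from 8.203 to 21.5 and 21.8. Mgl2, a lectin of macrophages and dendritic cells (chromosome 11, 69943859 to 69951044), went from 10.1 to 26.1 in both. Their log2 changes were 1.34 ± 0.11, 1.30 ± 0.10 and 1.29 ± 0.10 (SE), each with a limma adjusted p of 0.0413. The fourth, the microRNA gene Mir7091, chosen for naming after its values were seen, went from 30.5 to 139 and 109, with a log2 change of 1.98 ± 0.17 (SE) and a limma adjusted p of 0.0427. Its locus spans 71518556 to 71527672 on chromosome X, far longer than a microRNA, so its reads can belong to an overlapping gene. Med8 was the 1 gene that fell. Simulated libraries with no change gave 14.2 calls per run on average under noise as heavy-tailed as that between the hairpins. The total of 5 calls does not exceed that number. In the simulation a gene could take the noise of any gene of like level, so quiet genes could receive the noise of unstable ones. The median hairpin difference at each level was also taken out, while the main fit kept it (0.029 over all genes, shMed8.934 minus shMed8.933). The 14.2 calls therefore cannot decide how many of the 5 calls are false. Quantile normalization left 0 genes past limma's test, with 979 at an unadjusted p under 0.05, while the main test had 958 such genes. Median-of-ratios rescaling gave 37 that rose and 17 that fell. Unchanged libraries were fitted only without rescaling, and they lacked the offset between the hairpins that the main fit kept. They therefore match neither the main setting nor the alternatives in full, and the false calls to expect under each are unknown.

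**Figure D1:**
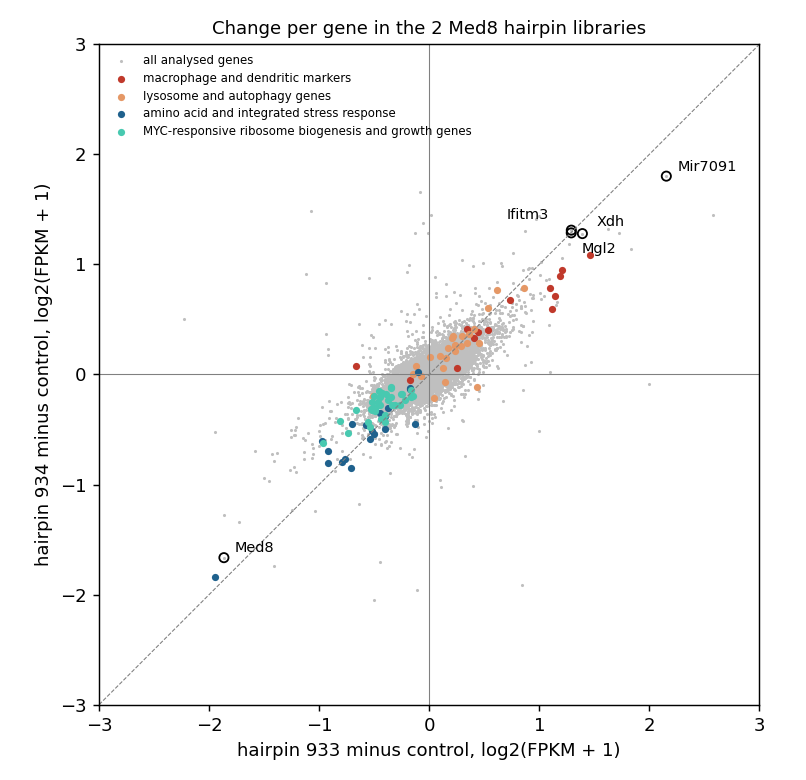
Each point is a gene, with its change in hairpin shMed8.933 (x axis) and hairpin shMed8.934 (y axis) against the shared control value, in log2(FPKM + 1); 4 gene lists are coloured, the 5 genes past the limma test are circled, the dashed line marks equal change, and 3 genes lie outside the range drawn. Med8 lies at -1.87 and -1.66, and the points lean along the dashed line with r = 0.70 across genes, against 0.50 simulated for unchanged libraries that share a control.

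The fold changes of the 2 hairpins went together across the 8057 genes. Pearson's r was 0.70 and Spearman's rho 0.72, and 76.9% of genes had the same sign. Unchanged libraries simulated against 1 shared control gave an r of 0.50 and 66.6% of the same sign. The covariance was 0.044, against 0.020 simulated (at most 0.025 in 100 simulations), a difference of 0.024. At least 1.5-fold higher in both hairpins were 63 genes, where simulation gave 18.5 (at most 32) and independent lists would share 1.96. At least 1.5-fold lower in both were 42 genes, against 18.5 simulated (at most 35) and 1.17. The counts at least doubled (12) or halved (8) in both lay within the simulated range, which reached 16 and 12. The control could not be split, so part or all of the excess may come from the shared control value.

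Markers of macrophages and dendritic cells were higher in both hairpin libraries. Of 33 listed, 14 were measured, with a median log2 change of 0.59 (0.63 with hairpin shMed8.933 and 0.51 with hairpin shMed8.934), and 12 were higher in both. The cathepsin Ctss was at 1.27 ± 0.17, the pore-forming protein Mpeg1 at 1.08 ± 0.15, the lysozyme Lyz2 at 1.04 ± 0.15 and the endotoxin co-receptor Cd14 at 0.71 ± 0.11 (SE). Csf1r, the receptor for macrophage colony-stimulating factor, was at 0.93 ± 0.19 and the integrin Itgam at 0.37 ± 0.12. None of the 14 passed over all genes, and 11 rose adjusted over the list alone. Median-of-ratios rescaling brought 5 past limma's test over all genes (Ctss, Mpeg1, Lyz2, Cd14 and Lyz1, adjusted p 0.0203 to 0.0422), and leaving out small RNA genes 3 (Ctss, Mpeg1 and Lyz2). The camera adjusted p was 9.6e-10, and the adjusted p was 0.813 with an estimated correlation. Lyz1 and Lyz2 are near-identical copies whose reads can be split between them.

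Lysosome and autophagy genes were also higher on balance, with a median of 0.23 over 26 measured genes, of which 19 were higher in both hairpins and 2 lower. Gns, which degrades heparan sulphate, was at 0.83 ± 0.11, and the cathepsins Ctsl and Ctsd at 0.69 ± 0.12 and 0.57 ± 0.12 (SE). None passed over all genes, except Gns under median-of-ratios rescaling and without small RNA genes, and these 3 rose adjusted over the list alone. Tpp1, a lysosomal peptidase, was at 0.41 ± 0.11. Camera gave an adjusted p of 3.7e-06, with an adjusted p of 0.813 with an estimated correlation.

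Genes of amino acid supply and the integrated stress response were lower in both hairpin libraries. Over 20 measured genes the median was -0.52, and 19 were lower in both. Atf4, the transcription factor at the centre of this response, went from an FPKM of 277 to 146 and 159. Its log2 change was -0.86 ± 0.13, that of its relative Atf5 -0.79 ± 0.11, that of asparagine synthetase Asns -0.77 ± 0.12 and that of Cth, which makes cysteine, -1.89 ± 0.21 (SE). None passed over all genes, with adjusted p-values from limma of 0.0843 for Cth and above for the others, and 16 fell adjusted over the list alone. Median-of-ratios rescaling brought 5 past limma's test over all genes, Cth (adjusted p 0.0143), Atf4 (0.0242), Atf5 (0.0243), Asns (0.0316) and Psat1 (0.0423), and Cth also passed without the trend, with a robust prior and without small RNA genes. The camera adjusted p was 3.1e-15, and the adjusted p was 0.813 with an estimated correlation.

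MYC-responsive genes of ribosome biogenesis and growth were lower in both libraries for all 35 measured, with a median of -0.35 (-0.44 with hairpin shMed8.933 and -0.27 with hairpin shMed8.934). Spermidine synthase Srm was at -0.80 ± 0.17, the folate carrier Slc19a1 at -0.64 ± 0.13, the nucleolar protein Gnl3 at -0.51 ± 0.11 and the ribosomal RNA processing factor Rrp9 at -0.49 ± 0.11 (SE). These 4 fell adjusted over the list alone, and none over all genes. Myc itself went from an FPKM of 91.6 to 73.2 and 73.3, a log2 change of -0.32 ± 0.12 that did not pass (limma adjusted p = 0.392). The camera adjusted p of the list was 3.1e-15, and the adjusted p was 0.813 with an estimated correlation. Cytosolic ribosomal protein genes had a median of -0.14, with 72 of 79 lower in both, and a camera adjusted p of 1.3e-07 (adjusted p = 0.813 with an estimated correlation). Quantile normalization brought their median to 0.0002. Rps26, Rpl38, Rps12 and Rpsa lay between -0.32 and -0.28, and many genes of this family have processed copies that can share reads.

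Cholesterol synthesis genes had a median of -0.37 over 25 genes, 21 of them lower in both hairpins, at -0.51 with hairpin shMed8.933 and -0.20 with hairpin shMed8.934. The receptor Ldlr was at -0.53 ± 0.11 and farnesyl diphosphate synthase Fdps at -0.76 ± 0.21 (SE), and 0 of 25 passed adjusted over the list alone. The camera adjusted p was 7.0e-08 (adjusted p = 0.813 with an estimated correlation). DNA replication genes had a median of -0.19, at -0.29 with hairpin shMed8.933 and -0.09 with hairpin shMed8.934, and 22 of 26 were lower in both. Their camera adjusted p was 0.000101 (adjusted p = 0.813 with an estimated correlation), and Tipin was at -0.53 ± 0.12 (SE). Mitosis genes had a median of 0.12, with 18 of 28 higher in both and 0 lower in both, and a camera adjusted p of 0.00182 (adjusted p = 0.813 with an estimated correlation); Cenpf was at 0.49 ± 0.13 (SE). Respiratory chain genes had a median of -0.13, at -0.21 with hairpin shMed8.933 and -0.04 with hairpin shMed8.934, and 42 of 62 were lower in both. Their camera adjusted p was 0.000265, and 0.0162 after a trend on transcript length was taken out. Unfolded protein response genes had a median of -0.18 and a camera adjusted p of 0.0270, and type I interferon genes a median of 0.20 over 8 genes and 0.0482. For these 3 lists the adjusted p was also 0.813 with an estimated correlation. Median-of-ratios rescaling ended the interferon call (0.0508), and quantile normalization ended the calls of the interferon, unfolded protein response, respiratory chain and ribosomal protein lists. No member of these 6 lists passed over all genes or adjusted over the list alone.

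**Figure D2:**
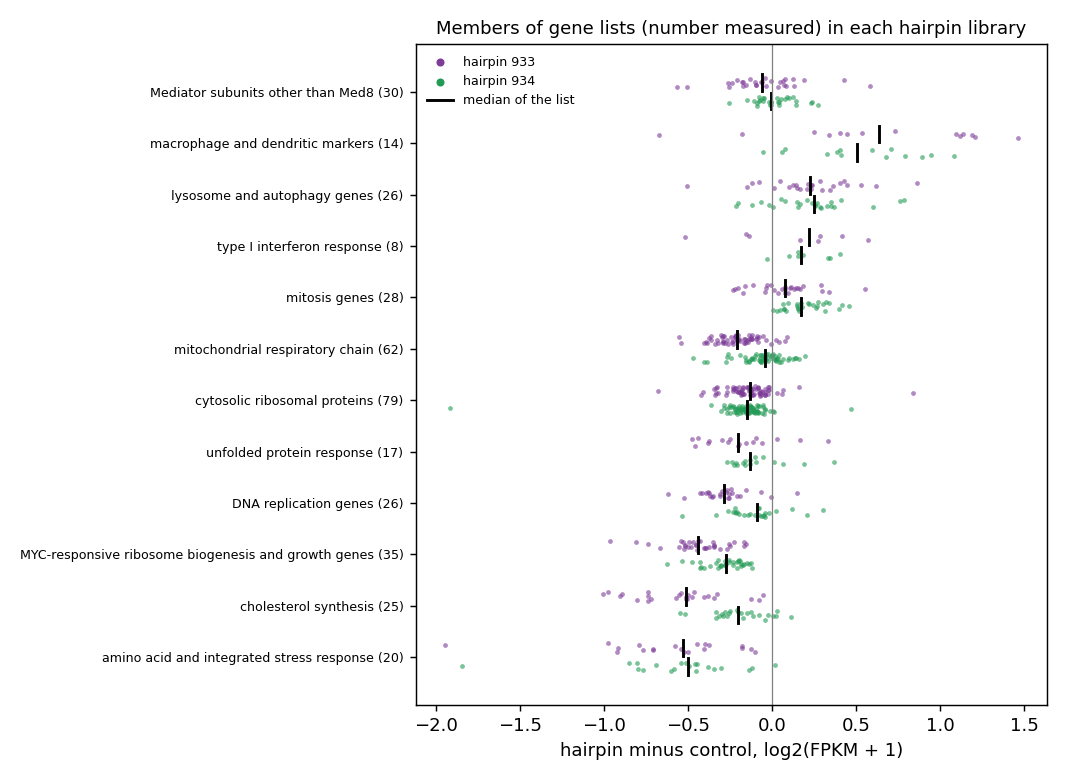
Each point is a measured member of a list, with its change against the control value in log2(FPKM + 1) (x axis), in hairpin shMed8.933 (purple) and hairpin shMed8.934 (green); black bars are list medians and the number of measured genes stands beside each name. The 11 lists past the camera threshold and the other Mediator subunits are shown; the medians of the stress response list are -0.53 and -0.50, and those of the Mediator list -0.06 and -0.01. The ribosomal protein median (-0.14) goes to 0.0002 under quantile normalization.

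The other Mediator subunits did not pass as a list. Their median was -0.04 over 30 genes, 0 passed adjusted over the list alone, and the camera adjusted p was 0.847. Cdk19 was at 0.43 ± 0.15 and Med11 at -0.38 ± 0.14 (SE). Med12, Med23 and Med24 were at 0.16, 0.07 and 0.05, and Med13 at 0.02, which turned to -0.02 under quantile normalization. Genes of RNA polymerase II and the general transcription factors had a median of -0.07 (camera adjusted p = 0.407), while Polr2a, the largest subunit of the polymerase, was at 0.82 ± 0.15 (SE; limma adjusted p = 0.178). BET and elongation factors had a median of 0.03 (0.442). Brd4 was at 0.0046, and Hexim1, an inhibitor of the elongation kinase P-TEFb, was at 0.60 ± 0.11 (SE) and rose adjusted over the list alone.

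Leukaemia oncogenes and myeloid transcription factors had a median of -0.02 (camera adjusted p = 0.775) and MLL-fusion targets one of 0.03 (0.442). Quantile normalization turned the first median to 0.01, and taking out the length trend turned the second to -0.01. Cdk6 was at 0.49 ± 0.12, Meis1 at -0.35 ± 0.11, Hoxa9 at -0.19 ± 0.13 and Bcl2 at 0.12 ± 0.11 (SE). Myb was at -0.02, which turned to 0.07 under quantile normalization. The homeobox gene Six1 was at 0.82 ± 0.12 (SE) and rose adjusted over the list alone, and over all genes under median-of-ratios rescaling. Stem and progenitor markers had a median of -0.02 (0.867), which turned to 0.07 under quantile normalization, while their mean was 0.01 and camera's direction was up. Kit was at -0.41 ± 0.22 (SE), with -0.13 in hairpin shMed8.933 and -0.68 in hairpin shMed8.934. Neutrophil granule genes had a median of -0.07 (0.0561), and median-of-ratios rescaling brought them past the camera threshold (0.0396). Prtn3 was at -0.80 ± 0.11 (SE) and fell adjusted over the list alone, and over all genes under median-of-ratios rescaling and without small RNA genes, while Mpo differed between the hairpins, at 0.11 with hairpin shMed8.933 and -1.03 with hairpin shMed8.934.

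Of the remaining lists, none passed the camera test. The adjusted p was 0.442 for p53 targets, 0.0520 for heat shock genes, 0.0727 for immediate early genes, 0.0910 for NF-kB genes, 0.353 for the Bcl2 family, 0.0565 for glycolysis, 0.399 for replication-dependent histones and 0.422 for common reference genes. Median-of-ratios rescaling brought the heat shock genes past the threshold (0.0367), and a mean FPKM of at least 5 brought them (0.0454) and glycolysis (0.0486) past it. The median of the reference genes was -0.11, which turned to 0.01 under quantile normalization. Among them, Actb was at -0.11 ± 0.11, which turned to 0.01 under quantile normalization, and Gapdh at -0.33 ± 0.17 (SE). The other 5 lists had fewer than 5 measured members: 3 for mast cells, basophils and eosinophils, 2 for nuclear-retained and mitochondrial RNA, 1 for erythroid cells and megakaryocytes, 1 for stromal and epithelial cells and 0 for lymphoid cells. Of these, the basophil protease Mcpt8 was at 0.96 ± 0.13 and the histamine-forming enzyme Hdc at -0.38 ± 0.12 (SE), and each passed adjusted over its list alone. Mcpt8 also passed over all genes under median-of-ratios rescaling and without small RNA genes. The nuclear RNA Neat1 was at 0.44 ± 0.12 (SE) and passed adjusted over its list alone, while Malat1 was at -0.38 with shMed8.933 and 0.21 with shMed8.934.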

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

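The control value sets the limit for every result, since it has no measured spread and depth is unknown. Leaving out either control library, or setting each hairpin against a different control library, was not run, because the table gives 1 control value. Leaving out a hairpin leaves no residual degree of freedom, so no counts or list tests were run without one. The Med8 change ranged from -1.87 to -1.66 with 1 hairpin left out, and with 2 hairpins such values always lie within 1 SD of the mean, so this says nothing about stability. Camera has no robust prior, so that setting was not run for the lists, and no count test was run since the table holds no counts. No paired analysis was possible because the groups share no replicate numbers. Leaving out small RNA genes, and the alternatives for genes doubled or halved, were chosen after the data were seen.

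The counts of called genes moved most, and the cause was not tested. Against 4 genes that rose and 1 that fell, quantile normalization gave 0 and 0, median-of-ratios rescaling 37 and 17, and leaving out small RNA genes 18 and 7. Limma without the trend gave 5 and 3, and with a robust prior 4 and 2. Under median-of-ratios rescaling all 5 genes were still called. The Med8 level changed by -1.78 under quantile normalization, with a limma adjusted p of 0.0811, and its adjusted p ranged from 0.00386 to 0.0811 over the alternatives. Of the 11 lists past the camera threshold, 7 passed under quantile normalization, and 0 with an estimated correlation (lowest adjusted p 0.813) and 0 with fry (lowest 0.350). The correlation of the hairpins was 0.74 without small RNA genes. Genes at least doubled in both hairpins went from 12 to 6 with a pseudocount of 5 and to 7 without small RNA genes, and genes at least halved from 8 to 3 with a pseudocount of 5.

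Under quantile normalization the direction turned for Hist1h2ag (0.019), Hist1h2an (0.073), Myb (0.071), Med13 (-0.020) and Actb (0.011), none of which passed limma's test over all genes, and camera's direction turned for the common reference genes (adjusted p 0.865). List medians turned for the reference genes (-0.11 to 0.01), the leukaemia oncogenes (-0.02 to 0.01), the stem and progenitor markers (-0.02 to 0.07) and, of the lists past the camera threshold, the ribosomal proteins (-0.14 to 0.0002). Camera kept these down (adjusted p 0.834). The neutrophil granule list passed camera under median-of-ratios rescaling (adjusted p 0.0396), a mean FPKM of at least 5 (0.0486) and leaving out small RNA genes (0.0396). Heat shock genes passed under these (0.0367, 0.0454 and 0.0396) and without the trend (0.0479), and glycolysis with a mean FPKM of at least 5 (0.0486) and without small RNA genes (0.0483). The run with no filter removed no gene and could change no result. Leaving aside it and the runs without a hairpin, the 124 named genes other than Med8 kept direction and side of the threshold in 959 comparisons, passed the threshold in 21, fell below it in 3 and turned in the 5 given above.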

Other observations

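The tests of other cells and of ribosomal RNA in the hairpin shMed8.934 library, and the test of a trend on the control value, were chosen only after the result was seen, and the genes of these first 2 paragraphs were chosen after their values were seen. Stfa2l1 was at -1.05 ± 0.16, BC100530 at -0.91 ± 0.27, Stfa2 at -0.88 ± 0.27 and Stfa1 at -0.84 ± 0.28 (SE). None passed limma over all genes, except Stfa2l1 under median-of-ratios rescaling (limma adjusted p 0.0242). These 4 genes are alike in sequence, so reads can be split between them, which was not tested. H2-D1 was at 0.85 ± 0.17, H2-L at 0.88 ± 0.15 and H2-Q4 at 0.72 ± 0.13 (SE). Again none passed, except H2-L under median-of-ratios rescaling (limma adjusted p 0.0433), and H2-D1 and H2-L have the same deposited locus. No fixed list holds any of these 7 genes.

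Several genes at least doubled or halved in both hairpins did not pass limma over all genes, but passed under median-of-ratios rescaling. Slfn4, an interferon-induced gene, was at 1.504, Rdm1 at 1.47, and Trf, which carries iron, at 1.13. Dach1, a transcriptional regulator, was at -1.14, Cftr at -1.57, Cox6a2 at -1.57 and P2rx3 at -1.24. The deposited locus of Cox6a2 spans 135317460 to 135349880 on chromosome 7, for a transcript of 680 nt, so its reads can belong to an overlapping gene. Under that rescaling the limma adjusted p of these 7 genes lay between 0.0118 (Rdm1) and 0.0282 (Cftr).

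Macrophage and lysosome genes were higher, and stress response and MYC-responsive genes lower, with a gap of 0.667 between the medians of 40 and 55 genes. Taking out a trend on transcript length left 98.2% of the gap (95% bootstrap interval 90.2 to 106.7), and a trend on GC content left 98.8% (95.9 to 102.04). This argues against a trend on these annotated values as the whole cause. The values are medians over a gene's annotated transcripts, so a trend on the length of the expressed transcript may have been taken out only in part. Taking out a trend on the control value over all genes left 99.5% (91.2 to 109.8), which argues against a smooth trend on that value as the whole cause. The trend was smoothed with a lowess span of 0.3, so it cannot decide on an effect confined to genes near the lowest listed control values. The check at a control FPKM of 10 or more (99.0%, 91.6 to 105.3) selects on that value again and decides nothing. A deviation of the single control value stays open: the covariance of the hairpins was 2.16 times the noise variance of 1 library, which a noisy control and a true effect of the knockdown both give. The pattern and this deviation cannot be told apart without control libraries that are measured one by one.

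Respiratory chain, general transcription factor and DNA replication genes were lower with hairpin shMed8.933 than with hairpin shMed8.934, by a median of -0.12 over 129 genes relative to all genes. Across all genes, shMed8.933 minus shMed8.934 did rise with transcript length (Spearman's rho 0.20) and fall with GC content (rho -0.11). The length trend ran from -0.029 at the 10th percentile of length to 0.050 at the 90th. Taking out the length trend left 90.9% of the lists' median difference (78.2 to 102.25), and taking out the GC trend left 103.8% (87.1 to 109.4). This argues against a trend on these annotated values as the whole cause. Among 10000 random lists matched on expression, the median of shMed8.934 minus shMed8.933 lay at percentile 100 for the respiratory chain list (0.16), 99.96 for DNA replication (0.18) and 98.86 for general transcription factors (0.10). The difference was not particular to these lists: cholesterol synthesis (0.40), neutrophil granule genes (0.29), mitosis (0.18) and MYC-responsive genes (0.17) lay at 100, heat shock (0.27) at 99.99, p53 targets (0.23) at 99.97 and glycolysis (0.19) at 99.96, while macrophage markers (-0.16) lay at 0, stem and progenitor markers (-0.13) at 0.34, leukaemia oncogenes (-0.06) at 0.59 and ribosomal proteins (0.0061) at 0.93. Members of a list can vary together, while genes drawn at random do not, so these percentiles can overstate how rare such medians are. Each hairpin has 1 library, so the difference has no replicate check, and no biological explanation was tested.

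The neutrophil granule list, whose median was 0.29 higher with hairpin shMed8.934 than with hairpin shMed8.933 (13 of 17 genes higher), held S100a8 at an FPKM of 3592 against 2538, S100a9 at 2286 against 1421 and Mpo at 1169 against 2563. Outside it, S100a4 was at 52.7 against 15.0, S100a6 at 16.8 against 7.13, Spp1 at 81.5 against 32.6, Ccr2 at 13.6 against 6.87, the macrophage marker Lgals3 at 35.5 against 20.7 and Kit at 27.4 against 40.4. Macrophage-like cells that diluted Mpo and Kit would lower alike those genes of the leukaemia cells that macrophages lack. The median of the MLL-fusion targets was 8.05% of the fall of Kit (-13.03 to 23.1). Only if macrophages lack these targets, which was not measured, does this argue against such cells as the whole cause of these 2 falls. Cdk6, Myb and Bcl2 are also in the list of leukaemia oncogenes and myeloid transcription factors, so the premise may fail for part of the targets. Even under that premise, a smaller share of the 2 falls stays open. The leukaemia oncogenes without Kit gave 8.01% (-8.48 to 38.8), but that list holds myeloid transcription factors that macrophages can share, so it decides nothing. For the stem markers without Kit (17.97%, -13.03 to 50.1) the interval passed the limit of 50% set for this test, so they decide nothing either. For the higher S100a4, S100a6, Spp1 and Ccr2 such cells stay open. The macrophage markers (median -0.163, -0.308 to -0.0526) cannot decide this, because they differed by more between knockdown and control than between the hairpins. Their control FPKM varied, with Lyz2 at 841 but Ctss at 15.5 and Cd14 at 17.7, against a median of 20.2 over all genes. The median over all genes, 5.33% of the smallest of the 6 differences of S100a4, S100a6, Spp1, Ccr2, Mpo and Kit, decides nothing about ribosomal RNA, since FPKM scaling holds it near 0; no biological explanation was tested, and with 1 library per hairpin the difference has no replicate check.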
